A study of Cucumis sativus var. sativus with 6 samples.

How the data were processed

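Messenger RNA of young cucumber fruit (pericarp and placenta of the pickling cultivar Vlaspik) was profiled by pyrosequencing, a method that reads cDNA fragments in comparatively long single reads. Per the labels, flowers of greenhouse plants were pollinated by hand on a single date, and fruits were taken at 0, 4, 8, 12 and 16 days post pollination (dpp). The 6 samples fall into 5 stages with 1 sample each, except for 8dpp with 2 samples. Per the labels' protocols, the experiment was repeated 3 times, but whether a library pools those repeats is not given in the sources used here. The sequencing accessions in the labels place both 8dpp samples under another submission than the other 4 samples.

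The authors deposited 1 table with 27471 contigs of a de novo assembly, each with its length, its total number of reads and 1 value per stage. Per the file headers, the stage values are in TPT, read here as transcripts per 1000 reads, that is, a contig's share of the reads of a stage times 1000. Per the file headers, total reads are whole-number counts summed over all libraries, and the deposited table gives no counts per stage. The authors rounded TPT to 2 decimals. The 2 samples of 8dpp share 1 column, so that no stage has a replicate and the spread between fruits, plants or libraries is unknown. The assembler, the read mapper and their versions are not given in the sources used here. The table pairs no contig with a gene name: 0 of the contig identifiers occur in the cucumber gene table used for names, and contigs are therefore given by identifier, without position or annotation. Gene lists for cell division, wall loosening, photosynthesis and other processes had been fixed before the data were examined, but none could be matched, and none was used.

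Stage depths were estimated from the table itself, since total reads must equal the sum over stages of TPT times the depth divided by 1000. A robust regression (Cauchy loss) over the contigs with at least 30 reads gave 235947 reads for 0dpp, 225191 for 4dpp, 186911 for 8dpp, 217283 for 12dpp and 202471 for 16dpp, with bootstrap standard errors of 342 to 695 reads over 100 resamples of contigs. Ordinary least squares gave 189042 to 233143 reads. With these depths, 1 step of 0.01 TPT stands for 1.87 to 2.36 reads. Stage values and total reads disagreed by more than rounding allows (5.34 reads) in 128 contigs, among them 39 of the 104 contigs with at least 1000 reads. This allowance holds no error of the estimated depths, which weighs most on abundant contigs. How many of the 128 such an error accounts for was not tested. The estimated depths sum to 1067804 reads, of which the 27471 contigs hold 925574, so that TPT is relative to reads in and outside the listed contigs.

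A contig's reads per stage were bounded by all whole numbers that round to the deposited TPT at the estimated depth. The ratio between 2 stages was given an exact 99% interval (Clopper-Pearson on the reads of one stage given the sum of both), taken at the least favourable of those whole numbers. A contig was called higher or lower when the bound nearest to 1 lay beyond 2-fold. This is a rule of size for these libraries: the interval covers counting error and rounding, not the spread between fruits, and no p-value was computed across contigs. Contigs with fewer than 30 total reads were left out, which kept 4999 contigs with 83.0% of all contig reads. A peak was called at a stage when TPT there was at least 2 times that of the stage with the next highest value and the 99% interval of the ratio to every other stage lay above 1. Correlations between stages used log2(TPT + 0.005) over the 4999 contigs, which are not independent replicates. Shares of reads have 95% Wilson intervals, which cover counting error only.

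With few exceptions named as such, the contigs named for each step are the 2 that rose and the 2 that fell with the most extreme bound, a rule fixed before the data were examined for a table without annotation. The calling rule, the filter, the stage comparisons and most alternatives were also fixed before the data were examined. That plan foresaw counts per stage scaled to the reads in contigs. TPT, a share of the reads of a stage, was used as deposited instead, and scaling to the sum of the listed contigs, the nearest to the plan, became an alternative, whose counts stand beside those of each step. The order of the stages, the timing of change, the shares of the most abundant contigs, the contigs that changed in several steps and the comparisons of stages that are neither neighbours nor the first and last were added after the data had been examined. The choice of scale was made after the sums of the stage columns had been seen, which are 952 TPT at 8dpp, 901 TPT at 16dpp and 811 to 839 TPT at the other stages. Rounding adds to the sums of 8dpp and 16dpp, as contigs with 1 read there were listed at 0.01 TPT: 227 contigs of 2 reads had 0.01 at both of these stages, and 0 had 0.01 at any other pair of stages. It does not account for the sum at 8dpp, where contigs with at least 30 reads hold 79.5% of the reads, against 64.8% at 0dpp, 71.0% at 4dpp, 73.8% at 12dpp and 72.0% at 16dpp. The data do not decide between both scales. A read at 16dpp rounds up to 0.01 TPT only at a depth of at most 200000 reads, below the estimate of 202471, and this depth was tried as an alternative. The contigs of 2 reads thus point to a 16dpp depth of at most 200000 reads. The estimate lies above it by more than its bootstrap standard error of 695 reads. At the estimate, 1 read was not among the whole numbers allowed for 0.01 TPT at 16dpp.

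The calls were tested on simulated tables, made from the contigs' mean values and the estimated depths and rounded like the deposited table. For the step from 0dpp to 4dpp (5072 contigs tested), 19% of 100 contigs with a true 4-fold change and 60% of 100 contigs with a true 8-fold change were recovered, with 0 false calls. For the step from 0dpp to 16dpp (5083 contigs tested) these shares were 23% and 57%. In 20 simulated tables without any stage effect, at most 1 contig was called in a step. When each library was given an added spread with a coefficient of variation of 25%, the mean was 4.2 to 5.65 calls per step, and with 50% it was 164 to 177 calls per step.

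Alternatives were TMM factors from edgeR 4.0.16 and median-of-ratios size factors from DESeq2 1.42.0, both computed on estimated reads rounded to whole numbers, leaving the 50 contigs with most reads out of the total, other filters, interval levels and folds, and the settings added later that the closing section names. The tests of edgeR and DESeq2 were not run, since there are no counts per stage and no replicates. Computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and R 4.3.3.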

Results

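The series followed the transcriptome of cucumber fruit through early development, with 1 column of values for each of 0, 4, 8, 12 and 16 days post pollination (dpp). Fruit at 0dpp is the ovary at flowering. Each stage rested on an estimated 186911 (8dpp) to 235947 (0dpp) reads. The 27471 contigs had a median length of 678 nt and a median of 6 reads over all stages, and the 4999 contigs with at least 30 reads entered the comparisons. No stage had a replicate, so that every difference below is one between libraries, with an interval for counting error and rounding only. Of the 4999 contigs, 848 (17.0%) were called higher or lower beyond 2-fold between at least 1 pair of stages.

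Transcript shares were most evenly spread over contigs at 0dpp and most concentrated at 8dpp. The 100 most abundant contigs of each stage held 16.7% of the reads at 0dpp (95% Wilson interval 16.5 to 16.8%), 19.7% at 4dpp (19.6 to 19.9%), 26.7% at 8dpp (26.5 to 26.9%), 21.4% at 12dpp (21.3 to 21.6%) and 20.7% at 16dpp (20.5 to 20.8%). The contig with the highest mean value over the stages, CuSa200910_2016 (1024 nt, named after its values were seen), went from 1.71 TPT (transcripts per 1000 reads) at 0dpp to 11.2 TPT at 4dpp and 25.5 TPT at 8dpp, and was at 14.0 TPT at 12dpp and 17.8 TPT at 16dpp. At 8dpp this 1 contig held 2.55% of the reads (2.48 to 2.62%). Relative to the reads in listed contigs alone, the 100 most abundant contigs held 20.6% at 0dpp and 28.0% at 8dpp, still the lowest and the highest of the 5 stages.

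The similarity of stages was compared across the 4999 contigs with at least 30 reads, where Pearson's r of log2 values was 0.748 between 0dpp and 4dpp, 0.653 between 4dpp and 8dpp, 0.745 between 8dpp and 12dpp and 0.832 between 12dpp and 16dpp. It was 0.426 between 0dpp and 16dpp, 0.581 between 4dpp and 12dpp, and 0.708 between 8dpp and 16dpp, above that of the neighbours 4dpp and 8dpp. These values depend on the filter: among contigs with at least 300 reads they were 0.139, 0.298 and 0.567, with 0.432 for 4dpp and 8dpp. With no filter they were 0.637, 0.767 and 0.706, the last then below the 0.740 of 4dpp and 8dpp. Without a filter, 4dpp and 12dpp (0.767) were more alike than 4dpp and 8dpp (0.740) or 8dpp and 12dpp (0.764), and 0dpp was more like 12dpp (0.692) than 8dpp (0.668). At 300 reads, 0dpp was less like 12dpp (0.101) than 16dpp (0.139). Spearman's rho gave 0.686, 0.594, 0.679 and 0.780 for the 4 neighbouring pairs and 0.398 for 0dpp against 16dpp. Rho for 0dpp against 16dpp was 0.192 with at least 300 reads and 0.522 without a filter. Among the 120 orders of the 5 stages, only the order by age and its mirror reached the observed mean correlation of neighbours (0.745; next highest 0.735), which gives p = 0.0167 in an exact permutation test, one-sided and the smallest p that 5 stages allow. This test was chosen after the correlations had been seen.

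**Figure D1:**
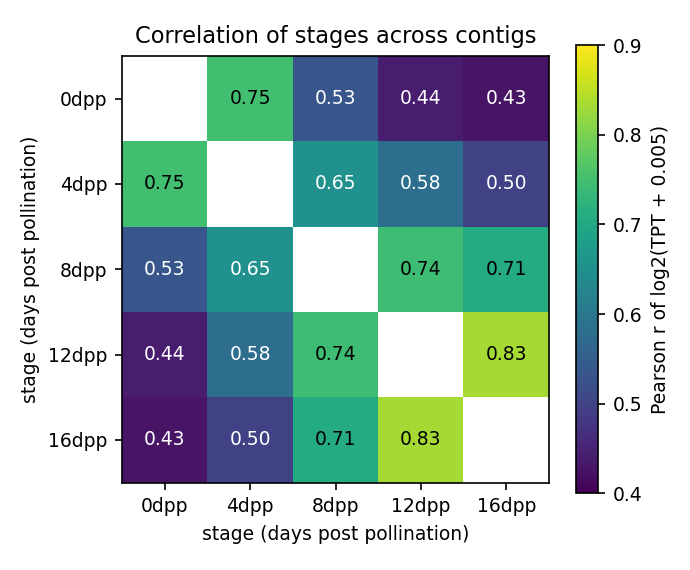
Pearson correlation of log2(TPT + 0.005) across 4999 contigs for each pair of stages (days post pollination on both axes, colour for r). Within each row, values decline away from the diagonal, and they range from 0.832 between 12dpp and 16dpp to 0.426 between 0dpp and 16dpp, and the lowest value between neighbours is 0.653 for 4dpp and 8dpp.

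The comparison of 0dpp with 4dpp covers fruit set, the first days after pollination. Of 4999 contigs, 68 were higher and 36 lower at 4dpp, while 4895 were not called (67 and 38 rescaled to the sum of the listed contigs). The strongest rise was that of CuSa200910_3277 (1050 nt), from 0.05 TPT at 0dpp to 3.64 TPT at 4dpp, 72.8-fold (99% interval 35.3 to 199.7). Its level remained high at 8dpp (3.23 TPT) and was 0.14 TPT at 16dpp. CuSa200910_2971 (1350 nt) rose 14.2-fold (9.71 to 21.7), from 0.22 to 3.13 TPT. Among the contigs that fell, CuSa200910_3017 (2294 nt) went from 5.21 TPT at 0dpp to 0.16 TPT, 32.6-fold lower (20.9 to 54.6), and CuSa200910_417 (896 nt) from 4.46 to 0.21 TPT, 21.2-fold lower (14.4 to 32.5). Both stayed at or below 0.13 TPT from 8dpp on. The stage values of CuSa200910_3017 and its total of 1346 reads disagree by 8.34 reads, beyond rounding.

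Between 4dpp and 8dpp, 150 contigs were higher and 63 lower, 213 in all and the most of the 4 neighbouring steps. CuSa200910_3301 (759 nt) rose from 0.01 TPT at 4dpp to 1.74 TPT at 8dpp (174-fold, 35.2 to 3812), and went on to 2.76 TPT at 12dpp and 4.19 TPT at 16dpp. Its stage values fall short of its 1863 total reads by 87.5 reads. CuSa200910_12937 (953 nt) rose from 0.01 to 1.66 TPT (166-fold, 33.6 to 3637) and was at 0.34 TPT at 12dpp and 0.13 TPT at 16dpp. CuSa200910_2790 (676 nt), at 0.96 TPT at 0dpp and 0.71 TPT at 4dpp, fell to 0.01 TPT at 8dpp (71.0-fold lower, 13.9 to 26820). CuSa200910_2971, which had risen at 4dpp, fell 12.5-fold (8.50 to 19.5), to 0.25 TPT at 8dpp. When values were rescaled to the sum of the listed contigs, which moved the median log2 ratio by -0.19, 113 contigs were higher and 102 lower, so that the share of rises went from 70.4% to 52.6%. Both 8dpp samples also belong to another submission than the other stages. Without that library, 277 contigs were called directly from 4dpp to 12dpp.

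Between 8dpp and 12dpp, 59 contigs were higher and 64 lower. CuSa200910_998 (941 nt) rose from 0.01 TPT at 8dpp to 1.31 TPT at 12dpp, 131-fold (26.0 to 49080), having been at 0.01 and 0.02 TPT at 0dpp and 4dpp. CuSa200910_8953 (728 nt) was listed at 0 at 0dpp, 4dpp and 8dpp and stood at 0.31 TPT at 12dpp and 0.63 TPT at 16dpp. Of the contigs that fell, CuSa200910_1432 (1542 nt) went from 1.09 to 0.07 TPT (15.6-fold lower, 7.75 to 35.2), and CuSa200910_1650 (1644 nt) from 2.15 to 0.19 TPT (11.3-fold lower, 7.37 to 18.1). The balance of rises and falls turned with a bound beyond 4-fold (15 higher and 11 lower) and with the scale: rescaled to the sum of the listed contigs, which moved the median by 0.16, 85 contigs were higher and 51 lower, so that rises made up 62.5% of the calls.

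Between 12dpp and 16dpp, 16 contigs were higher and 33 lower, the fewest of the 4 neighbouring steps (14 and 38 rescaled to the sum of the listed contigs). The excess of falls depends on the rule: 146 were higher and 128 lower with a ratio of at least 2 and an interval that excludes 1, and 5 and 5 with a bound beyond 4-fold. CuSa200910_2358 (894 nt) rose from 0.01 to 0.35 TPT (35.0-fold, 6.46 to 751), and CuSa200910_2667 (1565 nt) from 0.39 to 2.95 TPT (7.56-fold, 5.61 to 10.5), though its total of 977 reads minus the sum over its stage values is -13.4 reads. CuSa200910_2909 (1100 nt) fell from 4.94 to 0.31 TPT (15.9-fold lower, 11.4 to 23.2), after 1.26, 4.63 and 1.54 TPT at 0dpp, 4dpp and 8dpp. CuSa200910_998, which had risen at 12dpp, fell from 1.31 to 0.09 TPT (14.6-fold lower, 7.73 to 30.2). A simulated spread between libraries with a coefficient of variation of 50% and no stage effect gave at most 181 calls for 12dpp against 16dpp, 199 for 0dpp against 4dpp, 189 for 8dpp against 12dpp and 203 for 4dpp against 8dpp. The observed 49, 104 and 123 calls, any stage effect included, lie below the first 3 of these and the observed 213 above the last. A spread of 50% in every library thus gave more calls than those 3 steps show, and the setting is not fitted to the data. Without replicates the true spread is unknown.

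**Figure D2:**
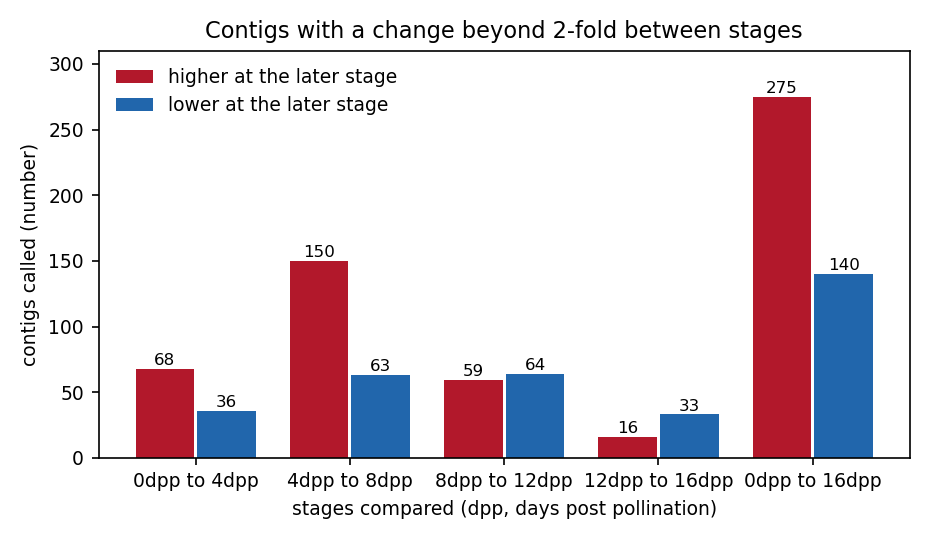
Number of contigs called higher (red) or lower (blue) at the later of 2 stages (vertical axis, of 4999 contigs tested) for the 4 neighbouring steps and for 0dpp against 16dpp. Calls are most frequent from 4dpp to 8dpp (150 and 63) and least from 12dpp to 16dpp (16 and 33), and 0dpp against 16dpp gives 275 and 140.

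Over the whole series, 275 contigs were higher and 140 lower at 16dpp than at 0dpp. CuSa200910_3301 was listed at 0 at 0dpp and reached 4.19 TPT, and CuSa200910_2152 (815 nt) was listed at 0 at 0dpp, had its highest value at 12dpp (2.69 TPT) and stood at 2.00 TPT at 16dpp. The strongest falls were those of CuSa200910_417, from 4.46 to 0.09 TPT (49.6-fold, 26.9 to 101.5), and CuSa200910_3017, from 5.21 to 0.13 TPT (40.1-fold, 24.1 to 72.0), both of which had also fallen by 4dpp. Rescaled to the sum of the listed contigs, which moved the median by -0.14, 237 contigs were higher and 164 lower. Calls grew with the time between stages when counted from 0dpp, with 104 at 4dpp, 323 at 8dpp, 407 at 12dpp and 415 at 16dpp.

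Among the contigs that differed between 0dpp and 16dpp, the step from 4dpp to 8dpp was the one that most often held the largest change. Relative to 0dpp, the 275 contigs that rose had a median log2 ratio of 0.80 at 4dpp (quartiles 0 and 1.82), 2.32 at 8dpp (1.54 and 3.70), 3.06 at 12dpp (2.10 and 4.25) and 3.38 at 16dpp (2.62 and 4.64). In 130 of the 275 (47.3%) the largest of the 4 steps was the one from 4dpp to 8dpp, against 75 for 0dpp to 4dpp, 52 for 8dpp to 12dpp and 18 for 12dpp to 16dpp. The 140 contigs that fell had medians of -0.60 at 4dpp, -2 at 8dpp, -3.03 at 12dpp and -3.30 at 16dpp, and 54 of them (38.6%) fell most from 4dpp to 8dpp. This timing rests on the 8dpp column, without which the steps on both sides of it cannot be resolved. These contigs were selected on their values at 0dpp and 16dpp, which favours the first and the last step. For the contigs that fell, values near 0 TPT leave little room for later falls. Their first quartile was -4.86 at both 12dpp and 16dpp.

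**Figure D3:**
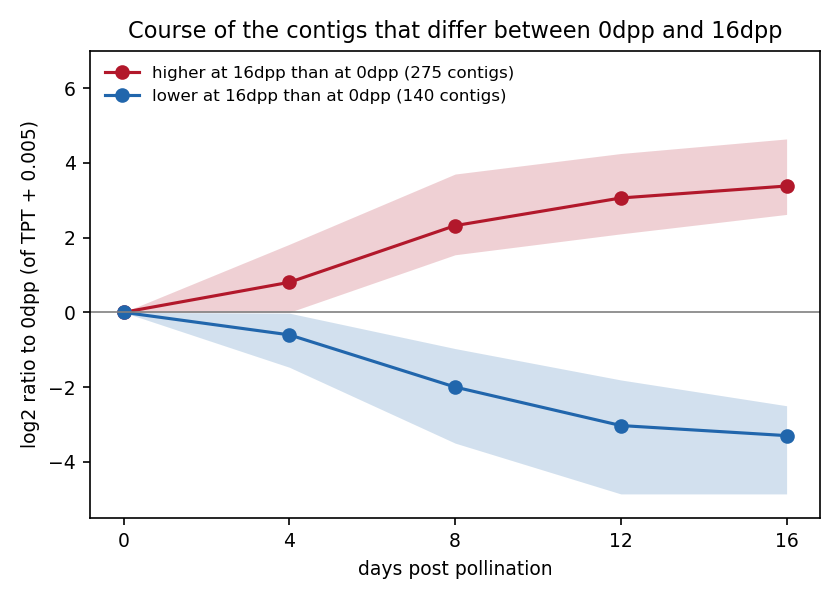
Median log2 ratio to 0dpp (vertical axis, of TPT + 0.005) against days post pollination for the 275 contigs higher (red) and the 140 lower (blue) at 16dpp than at 0dpp, with bands from the first to the third quartile over contigs. The red line climbs to 2.32 by 8dpp and 3.38 by 16dpp, and the blue line falls to -2 and -3.30.

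Peaks at a single stage were found in 259 of the 4999 contigs (5.18%). There were 76 at 0dpp, 48 at 4dpp, 70 at 8dpp, 21 at 12dpp and 44 at 16dpp. The 70 contigs with a peak at 8dpp held 8.05% of the reads of that stage (95% Wilson interval 7.93 to 8.17%), and the highest of them stood at 9.20 TPT. The 76 contigs with a peak at 0dpp held 3.29% (3.22 to 3.37%), and those of 4dpp, 12dpp and 16dpp held 2.04% (1.98 to 2.10%), 1.04% (1.00 to 1.09%) and 1.78% (1.72 to 1.84%). Rescaled to the sum of the listed contigs, 42 contigs peaked at 8dpp, fewer than the 91 at 0dpp and the 57 at 4dpp. Simulated tables without a stage effect had 0 contigs with a peak with counting error alone, a mean of 12.8 with a spread between libraries of 25% and a mean of 217 (at most 240) with a spread of 50%, against the 259 observed.

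Some contigs changed in both of 2 neighbouring steps, in opposite directions. Of the 150 contigs that rose from 4dpp to 8dpp, 22 fell again from 8dpp to 12dpp, where independent lists of these sizes would share 1.92, and 4 contigs fell and rose again over the same steps. At 4dpp, 8 contigs rose and fell and 5 fell and rose, and at 12dpp 10 rose and fell and 1 fell and rose. Both steps of such a pair use the middle library, so that noise in it enters both. Simulated tables without a stage effect gave 0 contigs that rose to and fell from 8dpp with counting error alone, and up to 25 with a spread between libraries of 50%.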

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

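The rescaling to the sum of the listed contigs, the depths from least squares, the 16dpp depth of 200000 reads, the calls without allowance for rounding, the leaving out of contigs that disagree with their total reads, the leaving out of 8dpp, the filter at 300 reads, median-of-ratios factors for the peaks, and all settings for the order of the stages, the timing (a higher pseudocount among them), the most abundant contigs and the contigs that rose and then fell were chosen after seeing the data. The 20 named contig comparisons, picked for extreme bounds, kept their call in all 254 alternative values. Many could not lose it: filters keep the interval, and the 95%, ratio and no-rounding settings only loosen the rule. Removed contigs are not counted. TMM factors, median-of-ratios factors, leaving the 50 most abundant contigs out of the total, no filter, least-squares depths, the 16dpp depth of 200000 reads, no allowance for rounding and leaving out the disagreeing contigs each kept every count of calls and peaks within 1.5 times. Rescaling to the sum of the listed contigs raised the falls from 4dpp to 8dpp to 102 and lowered the peaks at 8dpp to 42, since by construction it lowers values at 8dpp, whose column sum is the highest, more than at the other stages. The other counts moved with the strictness of the rule, in which fewer or more contigs can pass by construction. At 100 reads, falls numbered 18 from 0dpp to 4dpp and 41 from 4dpp to 8dpp, rises from 12dpp to 16dpp numbered 7, and peaks from 0dpp to 16dpp numbered 35, 27, 44, 11 and 25. With the 95% interval, 123 contigs rose from 0dpp to 4dpp, 114 fell from 4dpp to 8dpp, 90 rose and 103 fell from 8dpp to 12dpp, and 28 rose from 12dpp to 16dpp. With a ratio of at least 2 and a 99% interval that excludes 1, rises and falls numbered 308 and 212, 434 and 361, 254 and 307, and 146 and 128 in the 4 neighbouring steps, and 611 and 460 from 0dpp to 16dpp, so that rises outnumbered falls from 12dpp to 16dpp. With a bound beyond 4-fold they numbered 16 and 7, 48 and 8, 15 and 11, 5 and 5, and 108 and 44. With a peak ratio of at least 4, peaks numbered 24, 6, 20, 4 and 11, and with 8dpp left out there were 78 at 4dpp, 36 at 12dpp and 71 at 16dpp, as 1 stage fewer has to be exceeded. The order of the stages had p = 0.0833 in the exact permutation test without 8dpp, the smallest that 4 stages allow, and 0.0167 in every other setting. The share of rising contigs with their largest change from 4dpp to 8dpp was 54.0% at 100 reads, and the cause was not tested. Contigs that rose from 0dpp to 4dpp and fell from 12dpp to 16dpp numbered 48 with a ratio of at least 2 and an interval that excludes 1, where independent lists would share 7.89. Independent lists take no account of level: under the main rule, lists matched on mean level shared a mean of 1.38, against 0.449 for independent lists. Of 60 alternative correlations, 47 moved beyond the interval that 4999 contigs give (range of all 60 0.10 to 0.82, the lowest for 0dpp and 12dpp at 300 reads). Among the 60, Spearman's rho with another pseudocount could not move, as an added constant keeps the ranks. Not run were the tests of edgeR and DESeq2, the sums by annotation, the gene lists, and the agreement of the 8dpp samples or the leaving out of either, since the table has no replicates, no annotation and 1 column for 8dpp. No paired analysis was possible because each stage has 1 column. Depth limits the calls: of simulated 4-fold changes, 19% were recovered from 0dpp to 4dpp, 18% from 4dpp to 8dpp, 11% from 8dpp to 12dpp, 25% from 12dpp to 16dpp and 23% from 0dpp to 16dpp, and of 8-fold changes 60%, 59%, 66%, 63% and 57%.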

Other observations

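In this part, the tests on rounding at the step from 4dpp to 8dpp and on the 16dpp library were chosen after their results had been seen. A group of contigs rose at fruit set and fell at the last step, from 12dpp to 16dpp, 2 steps that share no library. Of the 68 contigs that rose from 0dpp to 4dpp, 8 fell from 12dpp to 16dpp, where independent lists would share 0.449 and 10000 random lists matched on mean level held at most 7. Their median values were 0.065 TPT at 0dpp, 0.465 at 4dpp, 0.99 at 8dpp, 0.605 at 12dpp and 0.11 at 16dpp. The 68 contigs also held 9 of the 64 contigs that fell from 8dpp to 12dpp (at most 5 in the central 95% of matched lists and at most 9 in any). Of the 12 overlaps computed in the family, 1 more exceeded the central 95% of its matched lists: 3 of the 63 contigs that fell from 4dpp to 8dpp also fell from 12dpp to 16dpp, against at most 2. Overlaps are described by their rank among random lists, without p-values.

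For the contigs that rose first and fell last, a high level at 12dpp, which makes a fall easier to call, gives too few: random lists matched on the level at 12dpp held a mean of 2.08 falls, at most 5 in their central 95% and at most 8 in any of the 10000 lists, against 8 observed. Counting 1 transcript as several contigs would give few profiles if its pieces share the same one. The 8 contigs showed 6 different profiles over the stages (chi-square p at or under 0.01 between profiles). However, the chi-square covers counting error only, and pieces of 1 transcript that differ beyond it would count as different profiles. The number of profiles therefore cannot exclude this explanation. A difference between the stages of the fruit, which was not tested, stays open beside the spread between plants, which no stage allows to be measured.

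The step from 4dpp to 8dpp had the most calls. If the 8dpp library alone stood apart, 4dpp and 12dpp would differ less than 4dpp and 8dpp. Instead 277 contigs were called directly from 4dpp to 12dpp against 213 from 4dpp to 8dpp. The difference is above the margin of 44.3 that a rule fixed before the count was seen gives. Thus 4dpp and 12dpp differed without the 8dpp library too. However, the first comparison spans 8 days and the second 4, so that change with age alone can raise the first. The counts also share the 4dpp library, which the margin ignores. They cannot tell whether a batch added calls at 8dpp. Across all listed contigs without a filter, 4dpp was more like 12dpp (Pearson's r of 0.767) than 8dpp (0.740), as a batch would give. For the number of calls, rounding is unlikely to be the cause, since among the 483 contigs with at least 300 reads the step had 86 calls, against 49, 51 and 25 in the other steps. A change of the fruit between 4dpp and 8dpp, an effect of the separate submission of 8dpp, and the spread between plants all stay open.

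Longer contigs rose more than shorter ones from 12dpp to 16dpp, with Spearman's rho of 0.147 across 4999 contigs, and the quintile of longest contigs had a median log2 ratio of 0.25 against 0 for the shortest. Rounding predicts no trend among abundant contigs, but rho was 0.162 with at least 300 reads. A trend with abundance is argued against by a partial rho of 0.14 given total reads. A 16dpp library that favours long contigs stays open: rho from 0dpp to 16dpp was 0.00734 over all 4999 contigs, but 0.0996 with at least 300 reads, where 4dpp and 8dpp to 16dpp gave 0.0906 and 0.055. A shift of the 12dpp library in fragment selection stays open too, as the values are mixed. Rho from 0dpp, 4dpp and 8dpp to 12dpp was -0.093, -0.0593 and -0.0187 over all 4999 contigs. With at least 300 reads it was 0.0426, 0.0273 and -0.0655. A difference between the stages was not tested and stays open as well.

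Among 66 changing contigs with at least 1000 reads, 7 of 2145 pairs had profiles that did not differ (chi-square p above 0.01). The pair CuSa200910_2902 and CuSa200910_3281, chosen after its values were seen, had its highest values at 8dpp with 8.83 and 9.20 TPT, with 0.36 and 0.33 TPT at 0dpp and 0.82 and 0.98 TPT at 16dpp. Whether such a pair belongs to 1 gene was not tested, as no sequences were used here.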
